A study of Homo sapiens with 6 samples.

How the data were processed

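The 6 libraries were prepared from ribosomal RNA-depleted total RNA of CCD-1064sk dermal fibroblasts with a stranded kit, per the labels' protocols. They came from 3 lines, NC, SH2 and SH3, each at rest and after 48 h of constant stretch, and the groups were taken from the labels. The labels do not spell out NC, which they give as wild type. The authors deposited FPKM values (fragments scaled by transcript length and by the number of mapped fragments) per gene and library, per the file headers. HISAT2 and StringTie were used on build hg19, per the submitters' processing notes, and their versions and settings are not given in the sources used here, nor is the annotation release. The gene identifiers have the form of GENCODE identifiers lifted to hg19, per the file headers. The table listed 12185 entries, all typed as protein-coding, and the lowest of the genes' highest FPKM values was 0.501, so genes below an FPKM of 0.5 in every library appear to have been left out before deposit. Noncoding RNAs were not analysed here. Whether the counting used the strand is not given in the sources used here, so overlapping genes, antisense partners and near-identical copies such as the PCDHG cluster are uncertain.

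FPKM values carry no read counts. Values of low genes times transcript length were compared with multiples of the value of 1 read, and 18.4% to 30.7% per library lay within 0.1 of a multiple where chance gives 20%. Whole reads were therefore not recovered, the depth is unknown, and no counting intervals or limits for low genes were computed. The sum of FPKM lay between 207188 and 232858 per library.

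For each symbol listed more than once the entry with the highest mean was used, which left 12178 genes. Values were transformed as log2(FPKM + 1), so fold changes are on that scale and understate the change of low genes, and 10834 genes with an FPKM of at least 1 in at least 2 libraries were tested. limma 3.58.1 in R 4.3.3 was used with a mean-variance trend and Benjamini-Hochberg adjustment at 0.05. The stretch effect over the 3 lines came from a fit of stretch plus knockdown with 3 residual degrees of freedom. The other 5 comparisons (stretch in NC, stretch in the shRNA lines, shRNA against NC at rest and under stretch, and the difference of the stretch effects) came from a fit of the 4 groups with 2 residual degrees of freedom. The 2 NC groups hold 1 library each, and their spread was taken from the shRNA groups. The median standard error of a log2 change was 0.19 for stretch over the 3 lines, 0.34 for stretch in NC, 0.24 in the shRNA lines, 0.29 for both comparisons of shRNA with NC and 0.41 for the difference.

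Of the gene lists fixed before the data were examined, 35 in number, 28 had at least 5 tested members and were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Camera compares the members of a list with the other genes, so the mean of a list minus that of other genes is given where a correction ended a call. The SE of a list mean is taken over the genes of the list. It treats them as independent and does not measure the spread between libraries. A camera test with an estimated correlation kept 0 of the 26 list calls. It takes that correlation from the 2 or 3 residual degrees of freedom of a fit, so hardly any list could pass. Its adjusted p-values therefore cannot decide whether a list changed, and the calls rest on the preset correlation. Members were also adjusted over their list alone. That adjustment does not cover the other lists and comparisons, so some passes can arise by chance. The lists covered contractile, collagen, matrix, protease, IL6 family, STAT3, YAP, SRF, TGF-beta, ERK, chemokine, interferon, cell cycle, stress, metabolic, ribosomal and mitochondrial genes and markers of 7 other cell types. Genes were also counted that changed at least 2-fold in all 3 lines with stretch, or in both shRNA lines in both conditions. The genes named in the text are those past the threshold (up to 10 per direction and comparison, changed in the same direction in every line compared), then, up to 10 per direction, those with the largest smallest change over the lines, then up to 4 members per list with the largest fitted change, and IL11RA, IL11, IL6ST, ACTA2, COL1A1, COL3A1, FN1, POSTN and TAGLN throughout. Genes without a symbol, genes on chromosome Y and XIST were never named, and a symbol listed more than once stands for its entry of highest mean. MT-ND6, PCNA, the markers CSPG4, RGS5, CD68 and CD14 and the overlapping genes GALT and PALM2-AKAP2 met no part of this rule in any comparison, and MT-ND3 met it only for stretch over the 3 lines. These were named after their values were seen. Every other named gene met the rule in at least 1 comparison, which was not checked to be the comparison of each printed value.

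The line was also used as a block. That left 1 residual degree of freedom for stretch in NC, stretch in the shRNA lines and the difference of the stretch effects. NC, SH2 and SH3 are separate lines of the study, so a stretched and a control library of one line are paired by design. The correlation, across genes, of their deviations from the mean of the 3 libraries of the same condition was 0.151 in NC, −0.214 in SH2 and 0.287 in SH3. Comparisons of shRNA with NC lines cannot be blocked. The alternatives fixed beforehand were a pseudocount of 0.1, no filter, an FPKM of at least 5, median-ratio scaling, quantile normalization, limma without the trend, the block, a 1.5-fold rule and leaving out each library or line. Without a shRNA library the fit of the 4 groups has 1 residual degree of freedom, from the remaining pair of shRNA libraries. Its p-values then change even where the library left out has no part in the comparison. After the data were seen, a correction for GC content and transcript length was added (natural splines with 4 degrees of freedom, per library, with values of the longest coding transcript in GENCODE for 10806 tested genes, 99.7%), as was leaving out each library in the list tests. That annotation is on another build, so it gave lengths, GC content and overlaps but no coordinates; all coordinates are those of the deposited table. Chance for differences that share the NC libraries was simulated with 200 sets of unchanged genes.

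The steps were tested on simulated data with 10834 genes. Of genes changed 2-fold, 56.7% were called for stretch over the 3 lines, 4.48% for stretch in NC, 40.3% for stretch in the shRNA lines, 11.9% and 16.4% for shRNA against NC at rest and under stretch and 1.49% for the difference of stretch effects. At 4-fold the shares were 98.5%, 73.1%, 98.5%, 86.6%, 92.5% and 38.8%. False calls over all folds were 20 of 190, 10 of 127, 14 of 172, 7 of 139, 10 of 149 and 11 of 102 calls. Genes with low or very high means were not among the changed ones, and the noise was independent between genes. These shares therefore do not hold for low genes such as IL11RA.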

Results

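Transcript levels of protein-coding genes were measured by RNA sequencing of ribosomal RNA-depleted total RNA in CCD-1064sk cells, a line of human dermal fibroblasts, the cells that make the collagen matrix of the skin. A line labelled NC, given as wild type, and 2 lines carrying IL11RA short hairpin RNAs (shRNAs), SH2 and SH3, were each cultured on a flexible membrane either at rest (control) or under constant stretch for 48 h, which gave 6 libraries. Whether NC carries a control shRNA is not stated in the labels. The groups held 1 library (NC control), 2 libraries (shRNA control), 1 library (NC stretch) and 2 libraries (shRNA stretch). The values were FPKM for 12185 protein-coding entries, and 10834 genes with an FPKM of at least 1 in at least 2 libraries were tested. Between 10211 and 10463 genes per library reached an FPKM of 1, and the mean correlation of a library with the other 5, across genes, lay between 0.945 and 0.965. Sequencing depth was unknown, because no counts came with the values. The NC line had no replicate within a condition, so its lone libraries were assumed to vary like the shRNA lines. The limma p-values measured the spread between libraries of different lines, which may be technical. The camera p-values compared the members of a list with other genes at the preset correlation. A small camera p-value therefore does not show that a list would shift again in other libraries.

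The share of FPKM on mitochondrially encoded mRNAs differed between libraries. It was 24.5%, 10.1% and 20.8% in the control libraries of NC, SH2 and SH3 and 14.0%, 19.96% and 16.4% in the stretched ones. Genes rich in GC were also measured unevenly. The correlation, across genes, of a gene's deviation from its mean with its GC content was −0.31 in control NC and 0.36 in control SH2, then 0.12 in stretched NC and −0.31 in stretched SH2, with −0.09 and 0.16 in SH3.

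The target of the knockdown was examined first. IL11RA (ENSG00000137070.17_3, hg19 chromosome 9, positions 34650699 to 34661889, plus strand) encodes the receptor subunit that binds interleukin 11. Its FPKM without stretch was 2.16 in NC, 1.19 in SH2 and 1.21 in SH3, or 55.2% and 55.9% of the NC value. Under stretch it was 3.57 in NC, 0.65 in SH2 and 1.62 in SH3, or 18.2% and 45.4% of NC, so all 4 shRNA libraries lay below the NC library of the same condition. The fitted log2 difference was −0.52 (SE 0.33) without stretch and −1.14 (SE 0.33) under stretch, and neither passed the limma test after adjustment (adjusted p = 0.66 and 0.99998). IL11RA overlaps GALT and a readthrough gene on the same strand, and GALT itself lay between 1.85 and 2.52 FPKM. IL11, the ligand, was measured at 1.13, 2.24 and 2.05 FPKM in control NC, SH2 and SH3 and at 1.36, 1.43 and 3.86 under stretch. IL6ST, the signalling partner shared by the IL6 family receptors, was at 85.5, 35.9 and 30.3 FPKM without stretch and 68.3, 66.99 and 51.7 under stretch.

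**Figure D1:**
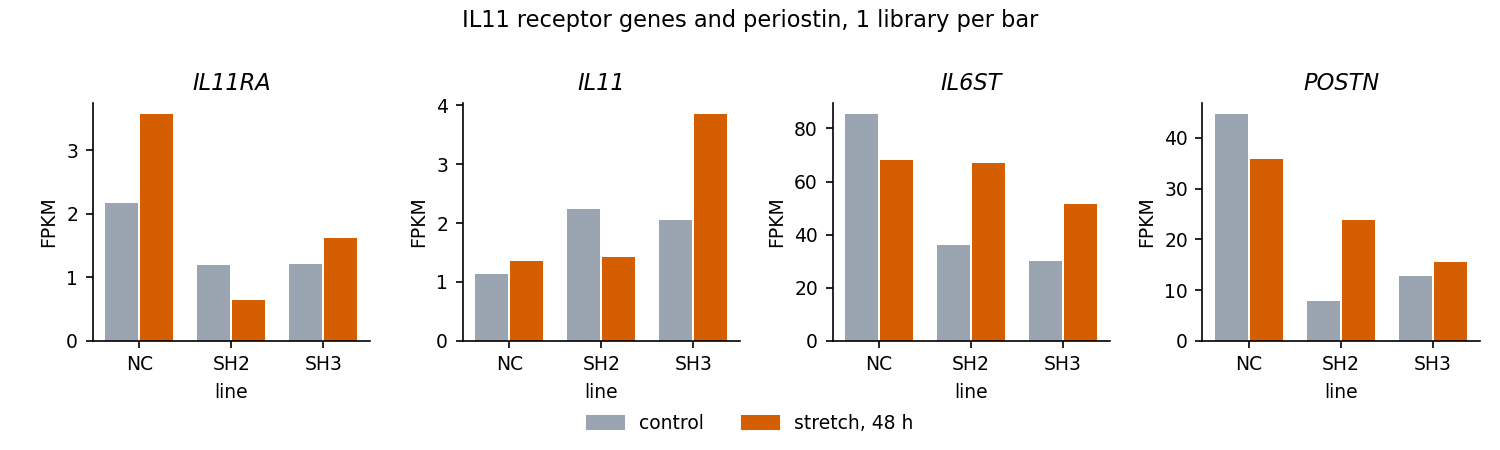
FPKM of IL11RA, IL11, IL6ST and POSTN in each of the 6 libraries, with 1 bar per library, grey for control and orange for 48 h of stretch, in the NC, SH2 and SH3 lines. IL11RA lay below the NC library of the same condition in all 4 shRNA libraries, at 18.2% of NC in stretched SH2.

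The first question was what 48 h of stretch changed in all 3 lines. Cell cycle genes rose, all 28 of them with a positive fitted change and 17 of them higher after stretch in each line (median log2 change 0.33, camera adjusted p = 6.1e-10; adjusted p = 0.84 with an estimated correlation). MKI67, a marker of proliferating cells, was at 1.45, 2.42 and 6.24 FPKM in control NC, SH2 and SH3 and at 2.10, 7.37 and 8.85 after stretch (log2 change 0.69, SE 0.30). The cyclins CCNA2 (0.52, SE 0.19) and CCNB1 (0.50, SE 0.22) and the mitotic activator CDC20 (0.49, SE 0.19) were higher after stretch in every line too. The list's median was 0.126 in NC, 0.477 in SH2 and 0.455 in SH3. None of its members passed the threshold over all genes and 0 did adjusted over the list alone.

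Chemokines and NF-kB targets rose as a list, with 15 of 17 members positive and 13 higher in all 3 lines (median log2 change 0.44, camera adjusted p = 0.0026; adjusted p = 0.84 with an estimated correlation). CXCL1, which attracts neutrophils, was at 3.32, 10.1 and 44.6 FPKM in control NC, SH2 and SH3 and at 14.999, 32.4 and 138 after stretch (log2 change 1.70, SE 0.66). CXCL8, another neutrophil attractant, was at 3.45, 7.98 and 167 FPKM at rest and 33.3, 32.7 and 199 after stretch (1.70, SE 1.15), and CXCL5 had a log2 change of 0.98 (SE 0.37). Adjusted over the list alone, 0 members passed. This call ended without the NC control library (adjusted p = 0.0603), the SH2 control library (0.881), the NC stretch library (0.0593) or the SH3 stretch library (0.334). Interferon stimulated genes, which cells use against viruses, rose as a list as well (16 of 20 positive, 4 higher in all 3 lines, median 0.30, camera adjusted p = 0.0242; adjusted p = 0.84 with an estimated correlation), with 0 members past the threshold adjusted over the list alone. Their median was −0.025 in NC against 0.429 and 0.420 in SH2 and SH3, and the call ended without the SH2 control library (0.920) or the SH3 stretch library (0.881). IFIT3, which restrains viral RNA, was at 48.3, 4.95 and 41.4 FPKM at rest and 43.6, 45.1 and 62.3 after stretch, so the SH2 control library had the lowest value. USP18, MX2 and OAS3 had log2 changes of 0.55 (SE 0.22), 0.46 (SE 0.22) and 0.44 (SE 0.22). Of the immune cell markers 2 were measured, with a median of 0.37. CD68 was at 32.0, 13.1 and 17.6 FPKM at rest in NC, SH2 and SH3 and 31.2, 19.8 and 30.6 after stretch (log2 change 0.43, SE 0.25), and CD14 at 1.63, 0.902 and 1.21 and then 2.07, 1.69 and 1.56 (0.31, SE 0.15).

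**Figure D2:**
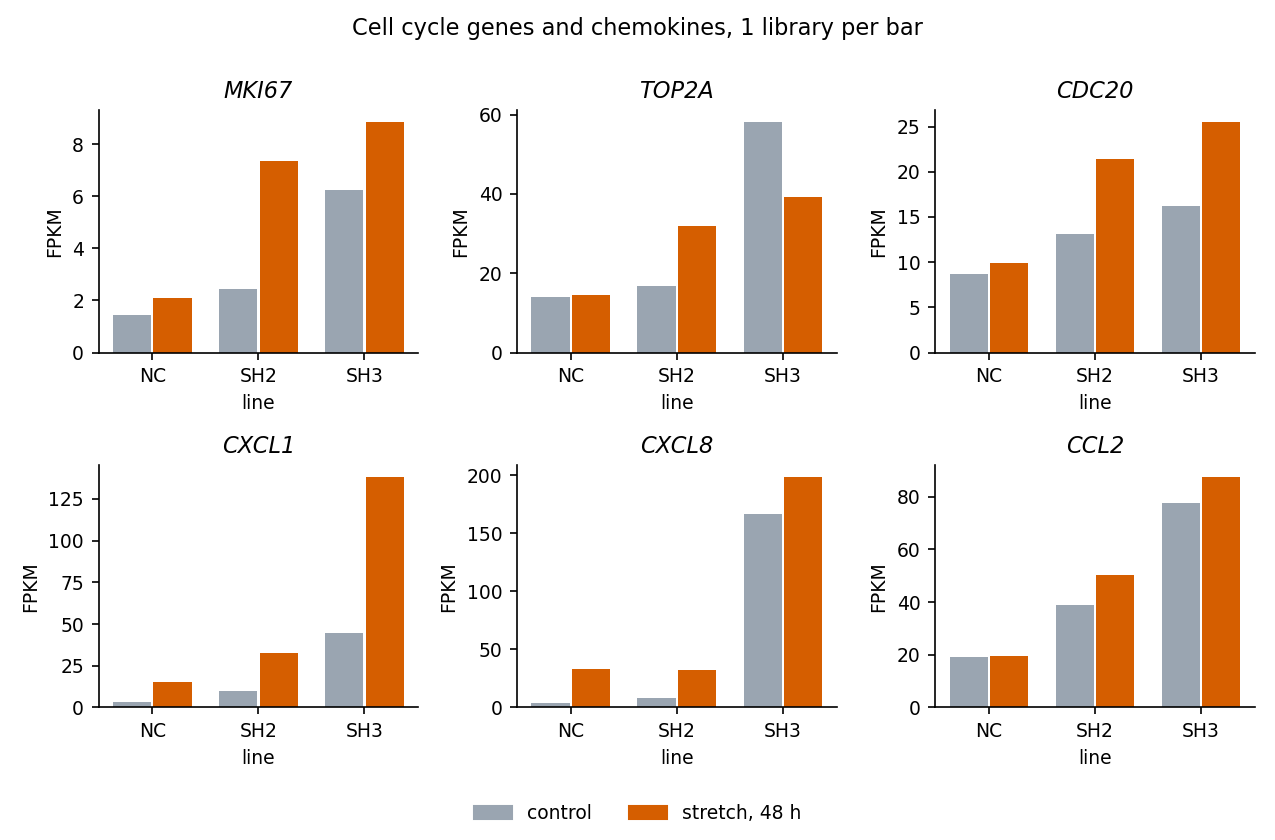
FPKM of 3 cell cycle genes (MKI67, TOP2A, CDC20) and 3 chemokines (CXCL1, CXCL8, CCL2) in each library, with 1 bar per library, grey for control and orange for 48 h of stretch. MKI67, CDC20 and CXCL1 were higher after stretch in each line, while TOP2A was at 58.2 FPKM in control SH3 and 39.1 in stretched SH3.

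The myofibroblast and matrix genes fixed for every comparison had these values over the 3 lines. ACTA2, the smooth muscle actin of myofibroblasts, was at 90.1, 141 and 104 FPKM at rest in NC, SH2 and SH3 and at 84.8, 120 and 107 after stretch (log2 change −0.09, SE 0.20). The log2 change was 0.11 (SE 0.30) for collagen COL1A1, 0.22 (SE 0.25) for COL3A1, 0.04 (SE 0.23) for fibronectin FN1, 0.48 (SE 0.32) for the matricellular protein POSTN and 0.06 (SE 0.30) for TAGLN, an actin-binding protein. IL11RA had 0.12 (SE 0.23), IL11 0.13 (SE 0.26) and IL6ST 0.44 (SE 0.28). The contractile and myofibroblast list did not pass (median 0.07, camera adjusted p = 0.710). Neither did the STAT3 targets (median 0.15, adjusted p = 0.239) or the TGF-beta list (adjusted p = 0.239), although 1 member of each passed when adjusted over the list alone. These were SOCS1, a feedback inhibitor of cytokine signalling that was at 8.72, 7.17 and 8.91 FPKM at rest and 17.0, 12.2 and 14.8 after stretch, and SKIL, a repressor of SMAD signalling that was at 1.95, 1.14 and 1.21 FPKM at rest and 2.75, 3.45 and 3.70 after stretch. With so many lists and comparisons, some members can pass over a list alone by chance.

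Gene by gene, limma called 0 genes for stretch over the 3 lines, and 219 genes had an unadjusted p under 0.05 (150 higher, 69 lower) where chance gives 542. That count was 907 without the SH2 control and 114 without the SH3 stretch library. The genes named by the size of their smallest change were led by CXCL1. Of the 20 genes picked by this rule here, 6 overlap a coding gene on the same strand. BTN3A2, a butyrophilin of immune cells, was at 1.26, 0.687 and 0.597 FPKM at rest in NC, SH2 and SH3 and at 3.34, 2.89 and 2.68 after stretch (log2 change 1.12, SE 0.15). GOLM1, a Golgi protein, had 0.85 (SE 0.18), CFLAR, an inhibitor of caspase 8, 0.85 (SE 0.17), and CSF2, the growth factor GM-CSF, 1.40 (SE 0.42). At the other end DAZAP2 was at 26.9, 14.1 and 14.1 FPKM at rest and 5.39, 6.64 and 7.56 after stretch (−1.31, SE 0.27). ARMCX3, a protein of the outer mitochondrial membrane, was at 37.9, 21.3 and 26.0 FPKM and then 14.3, 12.6 and 12.8 (−1.01, SE 0.19), and PLEKHB2 had −1.03 (SE 0.16). By the rule of at least 2-fold in all 3 lines, 3 genes were higher and 0 lower. Turning the sign of the NC line gave 7 and 2 genes, that of SH2 2 and 6, and that of SH3 1 and 1. The rule without a line gave 39 genes without NC, 33 without SH2 and 16 without SH3. With the sign of 1 of the remaining lines turned it gave 35, 25 and 68 genes.

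In the NC line alone, the question was what stretch did without an IL11RA shRNA. The collagens rose, with 18 of 20 measured members positive (median log2 change 0.31, camera adjusted p = 0.0205; adjusted p = 0.83 with an estimated correlation). COL1A1 was at 454 FPKM at rest and 721 under stretch (log2 change 0.67, SE 0.48), COL1A2 at 495 and 793 (0.68, SE 0.68), and COL8A1 and COL18A1, which are collagens of basement membranes and vessel walls, had 0.81 (SE 0.29) and 0.57 (SE 0.39). Ribosomal protein genes rose as well (23 of 26 positive, median 0.32, adjusted p = 0.00027; 0.83 with an estimated correlation), with RPS19 at 76.0 FPKM at rest and 172 under stretch. The mitochondrially encoded mRNAs fell (11 of 13 negative, median −0.88, adjusted p = 3.6e-05; 0.83 with an estimated correlation). MT-ND5, a subunit of complex I, went from 2624 to 867 FPKM, whereas MT-ND6 (177 and 303 FPKM) and MT-ND3 (1241 and 1446 FPKM) lay the other way. Adjusted over each list alone, 0 members passed. The library values moved with these lists, since the mitochondrial share was 24.5% in control NC and 14.0% in stretched NC and the correlation with GC content −0.31 and 0.12. After correction for GC content and length the collagen call ended (adjusted p = 0.0532), with a median of 0.19 and a list mean 0.23 above that of other genes (SE of the list mean 0.06) against 0.27 (SE 0.06) before. These errors are over genes and not over libraries.

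CXCL8 and CXCL1 had log2 changes of 2.95 (SE 2.04) and 1.89 (SE 1.22) in NC, ACTA2 −0.09 (SE 0.37), COL3A1 0.44 (SE 0.45), FN1 −0.37 (SE 0.37), POSTN −0.31 (SE 0.46) and TAGLN 0.38 (SE 0.54). IL11RA had 0.53 (SE 0.38), IL11 0.15 (SE 0.49) and IL6ST −0.32 (SE 0.35). AHNAK, which encodes a very large scaffold protein (ENSG00000124942.13_4, hg19 chromosome 11, positions 62201014 to 62323707, minus strand), was at 94.1 FPKM in control NC and 4.30 in stretched NC, and between 77.5 and 124 in the 4 shRNA libraries. SMIM3, a small membrane protein gene (hg19 chromosome 5, positions 150157508 to 150176296), was at 20.3 and 0.737 FPKM in NC and between 16.9 and 27.0 in the shRNA libraries. By limma 0 genes were called in the NC line and 207 had an unadjusted p under 0.05 (102 higher, 105 lower), or 789 without the SH2 control, 781 without the SH3 control, 139 without the SH2 stretch and 137 without the SH3 stretch library. With the line as a block, the pairing of each stretched library with the control of its own line, 7 genes passed, namely AHNAK, SMIM3, AKAP2, AC008878.1, AC010441.1, PCDHGC4 and PCDHGA8. The blocked fit had 1 residual degree of freedom. Without the SH2 control or the SH3 control library 1 gene passed. The chemokine and NF-kB list (15 of 17 positive, median 0.30) passed with the block (adjusted p = 8.5e-05) and not without it (0.202; 0.83 with an estimated correlation and no block). The contrast rests on 1 library in each condition.

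In the IL11RA shRNA lines, the same question was asked of the cells that carry an shRNA against the receptor. Cell cycle genes rose, with all 28 positive and 19 higher in both lines (median log2 change 0.47, camera adjusted p = 1.5e-06; adjusted p = 0.85 with an estimated correlation), among them MKI67 (0.87, SE 0.38), CDK1, the kinase that drives mitosis (0.65, SE 0.29), and the mitotic kinesin KIF20A (0.60, SE 0.21). Interferon stimulated genes rose (16 of 20 positive, 14 higher in both lines, median 0.53, adjusted p = 0.0081; 0.85 with an estimated correlation). MX1, an antiviral GTPase, was at 3.26 and 4.99 FPKM at rest in SH2 and SH3 and 5.39 and 9.64 under stretch. The immune cell markers CD68 and CD14 had log2 changes of 0.67 (SE 0.30) and 0.35 (SE 0.19). The interferon call ended without the SH2 control library (0.992) or the SH3 stretch library (0.910). Ribosomal protein genes fell (18 of 26 negative, 10 lower in both lines, median −0.21, adjusted p = 6.8e-05; 0.85 with an estimated correlation), with RPLP1 at 389 and 231 FPKM at rest and 135 and 198 under stretch, and the call ended without the SH2 stretch library (0.108). SRF and MRTF targets, genes of the actin cytoskeleton, fell (12 of 16 negative, median −0.10, adjusted p = 0.0268; 0.85 with an estimated correlation). ACTB was at 1530 and 1035 FPKM at rest and 878 and 1069 under stretch. The list's median was −0.198 in SH2 and 0.117 in SH3, the call was lost without the SH3 stretch library (0.479), and without the SH2 control library the direction turned (0.999). It also ended after GC and length correction (0.0890), although the median was −0.11 then, as the distance of the list mean from other genes went from −0.23 (SE of the list mean 0.06) to −0.19 (SE 0.07). In each of these 4 lists 0 members passed adjusted over the list alone.

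TIMP2, an inhibitor of matrix metalloproteases (ENSG00000035862.12_3, hg19 chromosome 17, positions 76849059 to 76921469, minus strand), was at 53.5 and 50.2 FPKM at rest in SH2 and SH3 and at 179 and 182 under stretch (log2 change 1.78, SE 0.22), and it passed adjusted over the list of protease inhibitors alone. TIMP2 overlaps CEP295NL on the same strand. SKIL passed adjusted over the TGF-beta list alone (1.07, SE 0.19). The chaperone gene HSPA2 was at 0.824 and 1.60 FPKM and then 9.18 and 6.93, and the transcription factor MAFF at 10.9 and 8.75 and then 1.52 and 3.197. IL6ST had a log2 change of 0.82 (SE 0.25), POSTN 0.88 (SE 0.33), COL1A1 −0.16 (SE 0.34), COL3A1 0.10 (SE 0.32), FN1 0.24 (SE 0.26), ACTA2 −0.10 (SE 0.26), TAGLN −0.10 (SE 0.38), IL11 0.13 (SE 0.34) and IL11RA −0.08 (SE 0.27). By limma 0 genes were called and 324 had an unadjusted p under 0.05 (226 higher, 98 lower), or 1359 without the SH2 control, 2245 without the SH3 control, 151 without the SH2 stretch and 181 without the SH3 stretch library. With the line as a block, at 1 residual degree of freedom, 10 genes passed, 7 of them higher (among them AKAP2, HSPA2, CLDN12 and MGME1). Others of the 10 included readthrough genes and PCDHG cluster members, whose values are uncertain, and clone-named entries. The chemokine list (14 of 17 positive, adjusted p = 2.3e-06, against 0.0594 without the block) passed too. So did the TGF-beta list (7 of 12 negative, 0.044, against 0.132), with a median of −0.214 in SH2 and 0.045 in SH3. With an estimated correlation and no block both had an adjusted p of 0.85. The chemokine list also passed without the block after median-ratio scaling (0.0114) or GC and length correction (0.0160). Without the SH2 control library 6 genes passed, and without the SH3 control library 20.

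**Figure D3:**
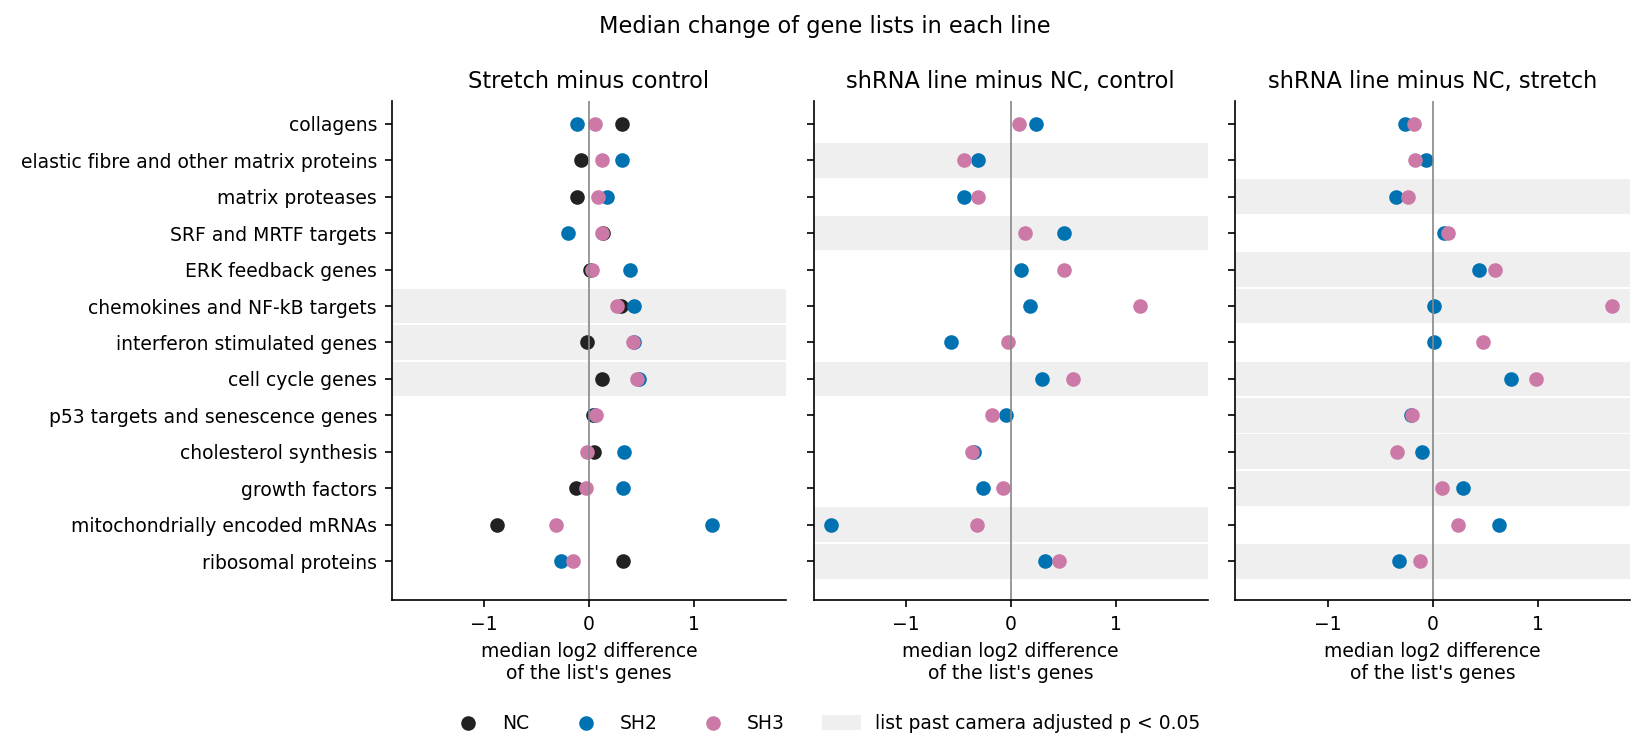
Median log2 difference, on the horizontal axes, of the tested members of each gene list that passed camera in at least 1 comparison, with 1 point per line for stretch minus control (left) and for each shRNA line minus NC at rest (middle) and under stretch (right), where grey bands mark the lists past the threshold. Cell cycle genes had a median of 0.739 in SH2 and 0.985 in SH3 relative to NC under stretch.

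The stretch changes of the lines were then compared with each other across genes, which are not independent replicates. The Spearman correlation of the changes was −0.51 between NC and SH2, 0.21 between NC and SH3 and −0.15 between SH2 and SH3. Of the 120 genes at least 2-fold higher after stretch in NC, such as CXCL8, 8.33% were so in SH2 and 13.3% in SH3, with a median log2 change of −0.40 in SH2 and 0.19 in SH3. The same step from other lines gave values in this range, since the 338 genes picked in SH2 had medians of −0.22 in NC and 0.00 in SH3, and the 164 genes picked in SH3 had 0.00 in NC and 0.17 in SH2. A gene picked for a high value in one line is lower elsewhere by selection alone, so these medians do not isolate an effect of IL11RA.

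**Figure D4:**
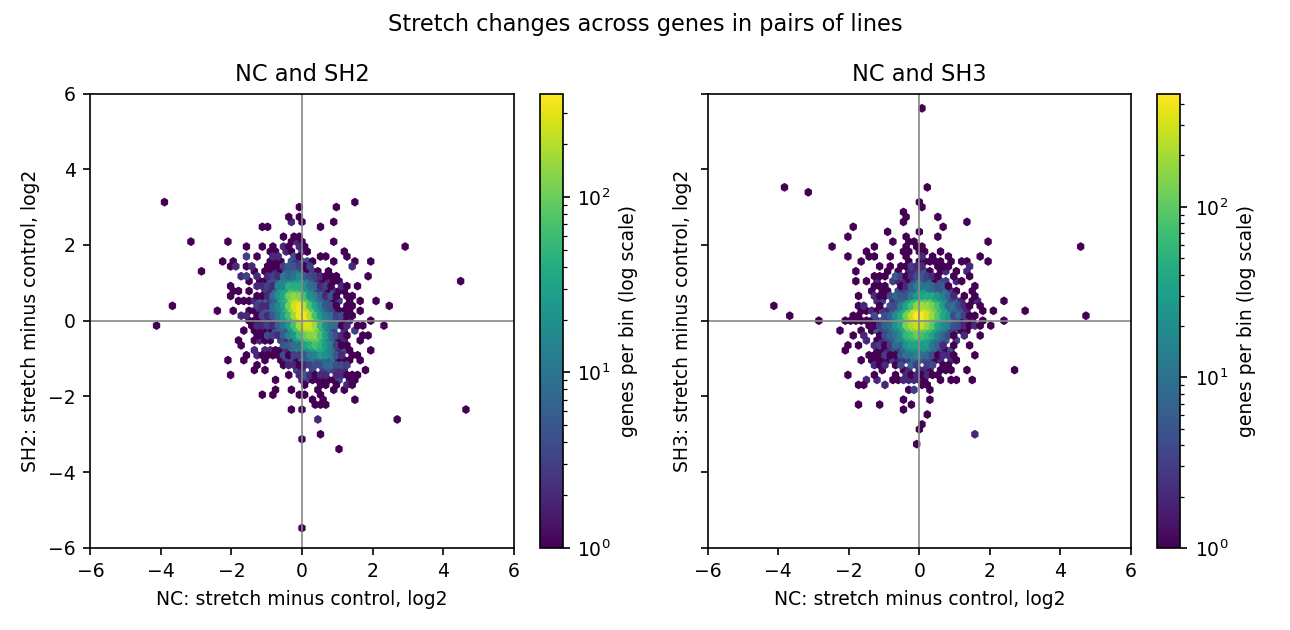
Log2 difference of stretch minus control for each tested gene in NC (horizontal) against SH2 (left) and SH3 (right), with color giving the number of genes per bin on a log scale. The cloud slopes downward for NC and SH2 (Spearman correlation −0.51 across genes) and upward for NC and SH3 (0.21).

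Without stretch, the shRNA lines were compared with NC to ask what differed at rest between cells with and without an IL11RA shRNA. Cell cycle genes were higher than in NC, with all 28 positive and 25 higher in both shRNA lines (median log2 difference 0.44, camera adjusted p = 3.1e-07; adjusted p = 0.64 with an estimated correlation). Both shRNA lines are set against the same NC library, so much of their agreement is given in advance. Over all genes 66.6% had the same direction in both shRNA lines at rest, and the simulation of unchanged genes gave 66.7%. TOP2A, the topoisomerase of dividing cells, was at 14.1, 16.8 and 58.2 FPKM in NC, SH2 and SH3, and E2F1, a transcription factor for entry into S phase, had a log2 difference of 1.29 (SE 0.38). Elastic fibre and other matrix proteins were lower (21 of 27 negative, 17 lower in both lines, median −0.31, adjusted p = 0.0297; 0.64 with an estimated correlation). EFEMP1, a fibulin, was at 52.6, 12.6 and 19.8 FPKM (−1.67, SE 0.36), whereas ELN, which encodes elastin, was at 0.446, 16.1 and 1.63. This call ended without the SH3 control, SH2 stretch or SH3 stretch library. The stretched libraries have no part in this comparison, so leaving out either of them changed only the estimate of the spread. SRF and MRTF targets were higher (13 of 16 positive, median 0.44, adjusted p = 0.0297; 0.64 with an estimated correlation), with ACTB at 644, 1530 and 1035 FPKM. The 4 measured markers of smooth muscle and pericytes, too few for a list test, had a median of 0.44, with 3 of them higher in both shRNA lines. CSPG4 was at 3.93, 8.51 and 9.06 FPKM and passed adjusted over the list alone, while RGS5 was at 1.46, 0.593 and 0.773. The immune cell markers CD68 and CD14 were both lower at rest in SH2 and SH3 than in NC, by the FPKM values given above. The call of the SRF and MRTF targets ended without the SH2 control (0.375), SH2 stretch (0.0744) or SH3 stretch library (0.0732). It ended after GC and length correction too (0.0734), with a median of 0.33 and a list mean 0.24 above other genes (SE of the list mean 0.12) against 0.31 (SE 0.12) before.

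Ribosomal protein genes were higher at rest in the shRNA lines than in NC (19 of 26 positive, 15 in both lines, median 0.38, adjusted p = 0.0018; 0.64 with an estimated correlation), with RPLP1 at 111, 389 and 231 FPKM in NC, SH2 and SH3, and the call ended after GC and length correction (0.0554), with a median of 0.24 and a list mean 0.29 above other genes (SE of the list mean 0.09) against 0.41 (SE 0.09) before. The mitochondrially encoded mRNAs were lower (11 of 13 negative, median −0.99, adjusted p = 0.0297; 0.64 with an estimated correlation), with a median of −1.71 in SH2 and −0.328 in SH3, and not without the SH2 control library (0.375). MT-ND5 was at 2624, 630 and 1111 FPKM, and MT-ND6 at 177, 467 and 252. In that library the mitochondrial share was 10.1% against 24.5% in control NC, and the correlation with GC content 0.36 against −0.31. In these 5 lists 0 members passed adjusted over the list alone.

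POSTN was the member of the contractile and myofibroblast list that passed adjusted over the list alone, at 44.8 FPKM in NC, 7.82 in SH2 and 12.7 in SH3 (log2 difference −2.06, SE 0.40, limma adjusted p = 0.632 over all genes). IL6ST passed adjusted over the list of the IL6 family alone (−1.35, SE 0.31), and MT2A, a metallothionein (1.75, SE 0.43), and HMOX1, the heme oxygenase (−1.18, SE 0.28), passed over the list of oxidative stress genes alone. None of these genes passed adjusted over all genes. COL1A1 had 0.04 (SE 0.42), COL3A1 −0.34 (SE 0.39), FN1 −0.31 (SE 0.32), ACTA2 0.42 (SE 0.32), TAGLN 0.42 (SE 0.46) and IL11 0.56 (SE 0.42). PRSS23, a serine protease (ENSG00000150687.11_3, hg19 chromosome 11, positions 86502101 to 86663952, plus strand), was at 5.85, 48.6 and 27.7 FPKM at rest in NC, SH2 and SH3 (2.46, SE 0.39). DAG1, the matrix receptor dystroglycan, was at 2.23, 11.5 and 13.3 FPKM, and CHRM2, a muscarinic acetylcholine receptor, at 18.8, 1.70 and 1.84. By limma 0 genes were called and 854 had an unadjusted p under 0.05 (376 higher, 478 lower), where chance gives 542. The count lay on either side of that value with 1 library left out, at 1815 without the SH2 control, 2932 without the SH3 control, 395 without the SH2 stretch and 389 without the SH3 stretch library.

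Under stretch, the same comparison gave the smallest adjusted p of any list in the 6 comparisons. Cell cycle genes were higher in both shRNA lines in 27 of 28 cases, and the list was higher than in NC (median log2 difference 0.86, 0.739 in SH2 and 0.985 in SH3, camera adjusted p = 1.2e-19; adjusted p = 0.63 with an estimated correlation). Over all genes 71.2% had the same direction in both shRNA lines under stretch, against 66.7% in the simulation of unchanged genes. MKI67 was at 2.10, 7.37 and 8.85 FPKM in stretched NC, SH2 and SH3 (1.55, SE 0.46), UBE2C, a ubiquitin enzyme of mitosis, at 7.61, 20.7 and 26.3, and CDC20 at 9.88, 21.4 and 25.5 (1.16, SE 0.29), while PCNA, the sliding clamp of replication, had −0.06 (SE 0.28). Of the 28 genes, 13 had an unadjusted p under 0.05 and 0 passed adjusted over the list alone. ERK feedback genes, which are induced by and dampen MAP kinase signalling, were higher (11 of 12 positive, 11 in both lines, median 0.53, adjusted p = 0.001; 0.63 with an estimated correlation; 0 adjusted over the list alone). DUSP4 was at 3.66, 5.97 and 6.32 FPKM, SPRY4 at 4.35, 7.88 and 7.24 and ETV4 at 0.936, 1.66 and 2.27.

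Chemokines and NF-kB targets were higher (14 of 17 positive, 9 in both lines, median 0.93, adjusted p = 0.0207; 0.79 with an estimated correlation), with a median of 0.013 in SH2 and 1.70 in SH3. CCL2, which attracts monocytes, was at 19.6, 50.2 and 87.5 FPKM in stretched NC, SH2 and SH3, and VCAM1, an adhesion molecule, at 4.92, 0.835 and 1.46 (−1.48, SE 0.29), the 1 member that passed adjusted over the list alone. This call ended without the SH2 control (0.0503) or the SH3 stretch library (0.548). Growth factors were higher (12 of 18 positive, median 0.27, adjusted p = 0.0484; 0.75 with an estimated correlation), with EREG at 14.6, 28.2 and 40.1 FPKM and HBEGF at 1.07, 2.32 and 2.88, both ligands of the EGF receptor. Their call ended without the SH2 control (0.0701), SH3 control (0.0691) or SH2 stretch library (0.182). After GC and length correction it ended too (0.0567), with a median of 0.23 and a list mean 0.21 above other genes (SE of the list mean 0.11) against 0.23 (SE 0.11) before.

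Other lists were lower in the stretched shRNA lines than in stretched NC. They were the p53 targets and senescence genes (12 of 13 negative, median −0.20, adjusted p = 0.0207; 0.63 with an estimated correlation), with the apoptosis gene BBC3 at 3.93, 2.06 and 2.47 FPKM and SESN1 at 8.64, 5.59 and 4.66 in NC, SH2 and SH3. Genes of cholesterol synthesis were lower (14 of 16 negative, median −0.26, adjusted p = 0.0249; 0.63 with an estimated correlation), with INSIG1, a sterol sensor, at 66.6, 39.1 and 41.2 FPKM. Both calls ended without the SH3 stretch library (0.132 and 0.253). Matrix proteases were lower (9 of 14 negative, median −0.37, adjusted p = 0.0484; 0.63 with an estimated correlation), with the collagenolytic protease CTSK at 954, 504 and 475 FPKM. That call ended with median-ratio scaling (0.0542) and without the SH2 control (0.0568), SH3 control (0.0577) or SH2 stretch library (0.262). Ribosomal protein genes were lower (25 of 26 negative, median −0.21, adjusted p = 0.0074; 0.75 with an estimated correlation), with RPS19 at 172, 94.6 and 117 FPKM, and not without the SH2 stretch library (0.313). Adjusted over each of these lists, and over that of the growth factors, alone, 0 members passed.

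COL1A1 was at 721, 427 and 402 FPKM in stretched NC, SH2 and SH3 (log2 difference −0.80, SE 0.42) and COL3A1 at 229, 154 and 132 (−0.68, SE 0.39). POSTN had −0.86 (SE 0.40), FN1 0.30 (SE 0.32), ACTA2 0.41 (SE 0.32), TAGLN −0.06 (SE 0.46), IL11 0.54 (SE 0.42) and IL6ST −0.21 (SE 0.31). TIMP2 passed adjusted over the list of protease inhibitors alone (1.72, SE 0.27). AHNAK had a log2 difference of 4.29 (SE 0.36, limma adjusted p = 0.0726) and rested on the low value of the stretched NC library, 4.30 FPKM. CXCL14, a chemokine of skin (ENSG00000145824.12_2, hg19 chromosome 5, positions 134906369 to 134914969, minus strand), was at 19.0, 5.51 and 4.67 FPKM (−1.72, SE 0.26), and the small GTPase gene RAB31 at 17.8, 4.36 and 3.01. By limma 0 genes were called and 365 had an unadjusted p under 0.05 (242 higher, 123 lower), and leaving out 1 library at a time gave between 0 and 4 called genes. The count at an unadjusted p under 0.05 was 1009 without the SH2 control, 1004 without the SH3 control, 231 without the SH2 stretch and 155 without the SH3 stretch library.

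Some differences between the shRNA lines and NC held in both conditions. At least 2-fold higher in both shRNA lines at rest and under stretch were 10 genes, and 6 were at least 2-fold lower. PRSS23 was at 5.06, 34.3 and 29.2 FPKM under stretch in NC, SH2 and SH3, beside 5.85, 48.6 and 27.7 at rest. The NC libraries are shared by these differences, and in 200 simulated sets of unchanged genes the rule gave a mean of 0.76 and 0.87 genes. With SH2 in the place of NC as the reference the rule gave 4 and 1 genes, and with SH3 2 and 7. At rest 29.5% of genes were higher in both shRNA lines and under stretch 35.8%, where the simulation gave 33.3%. The simulated differences share the NC libraries too, so the sharing itself is already in these chance values. The NC libraries are single and could not be divided, so a deviation of their own could not be separated. The simulated sets held no lasting difference between lines. An excess over them can therefore come from any stable difference between the lines, not only that of IL11RA.

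The last comparison asked whether stretch acted differently in the shRNA lines and in NC. AKAP2, an anchoring protein for protein kinase A (ENSG00000241978.9_3, hg19 chromosome 9, positions 112810878 to 112934792, plus strand), was the 1 gene that limma called (log2 difference of the stretch effects 7.23, SE 0.41, adjusted p = 0.0229). Its FPKM was 51.1 in control NC and 2.53 in stretched NC, against 4.12 and 46.3 in SH2 and 4.51 and 61.0 in SH3. AKAP2 overlaps the readthrough gene PALM2-AKAP2 on the same strand, which lay between 0.546 and 1.92 FPKM. After correction for GC content and length the log2 difference was 7.02 (SE 0.41) and the call ended (adjusted p = 0.0785), since the error was as before while limma's prior degrees of freedom went from 4.02 to 3.31. With the correction and the block together it passed (adjusted p = 1.8e-05). The error was larger there (SE 0.49), with 1 residual degree of freedom and 12.3 prior degrees of freedom. Without the SH2 stretch library (adjusted p = 0.0506) or the SH3 stretch library (0.073) it ended too and 0 genes passed, while 4 passed without the SH2 control and 2 without the SH3 control library. With the line as a block, again at 1 residual degree of freedom, 14 genes passed, 9 of them with a positive difference (among them AHNAK, SMIM3 and CLDN12). Others of the 14 included a readthrough gene and PCDHG cluster members, whose values are uncertain, and clone-named entries. At an unadjusted p under 0.05 there were 334 genes (173 positive, 161 negative), or 911 without the SH2 control, 2170 without the SH3 control, 148 without the SH2 stretch and 219 without the SH3 stretch library.

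Collagens had a lower stretch effect in the shRNA lines than in NC (13 of 20 negative, all 13 in both lines, median −0.33, camera adjusted p = 0.0244; adjusted p = 0.95 with an estimated correlation). Both line differences subtract the same NC change, so agreement of SH2 and SH3, here and in the lists that follow, is partly given in advance. COL7A1, the anchoring fibril collagen, had −0.94 (SE 0.51), COL8A2 −0.90 (SE 0.37), COL1A1 −0.83 (SE 0.59) and COL3A1 −0.33 (SE 0.55). The collagen call ended without the SH2 control (0.0673) or the SH3 stretch library (0.0854). It ended after GC and length correction too (0.0542), although the median was −0.49 then, as the distance of the list mean from other genes went from −0.37 (SE of the list mean 0.11) to −0.29 (SE 0.11). Ribosomal protein genes also had a lower effect (23 of 26 negative, 19 in both lines, median −0.52, adjusted p = 2.7e-06; 0.95 with an estimated correlation), with RPLP1 at −1.88 (SE 0.61). The mitochondrially encoded mRNAs had a higher one (11 of 13 positive, in both lines, median 1.40, adjusted p = 0.0018; 0.95 with an estimated correlation), with MT-ND5 at 2.17 (SE 0.70), while MT-ND6 had −0.97 (SE 0.65). Adjusted over each of these lists alone, 0 members passed. The mitochondrial share of FPKM went from 24.5% to 14.0% in NC, from 10.1% to 19.96% in SH2 and from 20.8% to 16.4% in SH3. As labelled, the shRNA lines thus went opposite ways, with a median stretch change of the mitochondrially encoded mRNAs of 1.17 in SH2 and −0.32 in SH3, against −0.88 in NC. An exchange of the SH2 control and stretched libraries, which stays open, would turn the SH2 value into a fall. POSTN had a difference of 1.19 (SE 0.56), IL6ST 1.14 (SE 0.43), FN1 0.61 (SE 0.45), IL11RA −0.61 (SE 0.46), TAGLN −0.48 (SE 0.66), ACTA2 −0.01 (SE 0.45) and IL11 −0.02 (SE 0.60). TIMP2 passed adjusted over the list of protease inhibitors alone (2.04, SE 0.38). Its passes here, for stretch in the shRNA lines and for shRNA against NC under stretch share the same stretched shRNA libraries. The cell cycle list, which passed in the shRNA lines and not in NC (adjusted p = 0.192), did not pass in the test of the difference (median 0.31, adjusted p = 0.208).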

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

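The splits of the libraries for the counts of genes and for the cell cycle list, the corrections for GC content and length, the tests of single lines and of an exchange of the SH2 libraries, and the test of the AKAP2 partner were chosen after the results were seen. The split of the list count, the check of low values in the NC and SH2 correlation and the other tests of overlapping genes were set beforehand.

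In 4 results the stretch effect differed between the shRNA lines and NC in a test of the difference itself. AKAP2 had a difference of 7.23 on the log2 scale, the collagens a median of −0.33, the mitochondrially encoded mRNAs 1.40 and the ribosomal protein genes −0.52. Each rests on 1 control and 1 stretched library of NC. With an estimated correlation the 3 list calls ended (adjusted p = 0.95 for each). After GC and length correction the collagen call ended (0.0542, with a median of −0.49), as did that of AKAP2 (0.0785, with a difference of 7.02). The collagen call also ended without the SH2 control (0.0673) or the SH3 stretch library (0.0854), and that of AKAP2 without the SH2 stretch (0.0506) or the SH3 stretch library (0.073).

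Cell cycle genes were higher in both shRNA lines under stretch (median log2 difference 0.86, camera adjusted p = 1.2e-19, and adjusted p = 0.63 with an estimated correlation, which ends the call). A trend with GC content and length as the whole cause is argued against by the corrected median of 0.828, still past the threshold at the preset correlation, and a change in a single shRNA line by the smaller of the line medians, 0.739. Both medians are taken from the same stretched NC library, where chance alone gives 66.7% of genes the same direction in both lines, so a deviation of that library stays open. A difference between the lines other than IL11RA stays open, because the list was also higher at rest (smaller line median 0.296) and the design holds 1 NC line. Lower IL11RA mRNA in the shRNA lines, at 18.2% and 45.4% of NC under stretch and not past the threshold (limma adjusted p = 0.99998), stays open and untested, because line and knockdown are confounded.

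Stretch changes in NC and SH2 ran in opposite directions across genes (Spearman correlation −0.51). A trend with GC content and length as the whole cause is argued against by a correlation of −0.419 after its removal, and noise of low genes by −0.568 over genes with an FPKM of at least 5. An exchange of the control and stretched SH2 libraries cannot be told apart from a true difference, since 8 genes changed at least 2-fold in all 3 lines with the sign of SH2 turned, 9 with that of NC turned and 3 as given, and the order of the turned counts changed with the setting (21 for SH2 and 17 for NC with a pseudocount of 0.1, 56 and 29 at 1.5-fold, 6 and 11 after GC and length correction). Both correlations that involve SH2 were negative (−0.51 and −0.15), and that of NC and SH3 was 0.21. As given, the mitochondrial share fell with stretch in NC (24.5% to 14.0%) and SH3 (20.8% to 16.4%) and rose in SH2 (10.1% to 19.96%). The correlation with GC content rose in NC (−0.31 to 0.12) and SH3 (−0.09 to 0.16) and fell in SH2 (0.36 to −0.31). IL11RA rose in NC and SH3 and fell in SH2. An exchange would align all 3 lines on these values. The cell cycle and chemokine lists go the other way, with positive medians in all 3 lines as given. With the SH2 libraries exchanged, limma gave 1102 genes at an unadjusted p under 0.05 for stretch over the 3 lines, against 219 as given. It gave 546 with the NC libraries exchanged and 133 with those of SH3. With the SH2 exchange 0 genes and 1 list passed, against 0 genes and 3 lists as given. A true opposite response of SH2 would give such values too. No other test separates a biological difference between the lines from a difference between single cultures. Of the 26 list calls, 9 ended and 1 turned without the SH2 control library, 10 ended without the SH3 stretch library and 6 without the SH2 stretch library.

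The 200 genes with the largest range over the libraries, among them AKAP2, may partly reflect how reads of overlapping genes were assigned. Of those genes, 34.2% overlap a coding gene on the same strand against 11.2% of other tested genes (Fisher's exact test, two-sided, p = 2.7e-17), and the median correlation with the overlapping partner over the libraries was −0.593, below the middle 95% of 1000 sets of random partners (−0.165 to 0.2299). The partner made up a median share of 0.323 of a gene's swing in FPKM times length, and the rest was not accounted for by the listed partner. For AKAP2 itself that share was 0.0143, which argues against reads moving to PALM2-AKAP2, and assignment to transcripts not listed stays open. For the 131 genes without an overlap low values stay open, because the 4.58% with a highest FPKM under 5 decide nothing where the choice by range already requires a highest FPKM of at least 2.99. Of the 20 genes that the naming rule picked by threshold or size in each comparison, 6 to 11 overlap a coding gene on the same strand.

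For stretch over the 3 lines, the 6 libraries allow 10 splits into groups of 3, too few for a share under 0.05. The real split and 3 others put 1 library of each line in each group, as the pairing by line does. Among these 4, the real split called 0 genes against a highest other value of 1, gave 219 genes at an unadjusted p under 0.05 against 1102, and gave 3 lists against 6. The cell cycle list had an adjusted p of 6.1e-10 in the real split, and the smallest of those 3 others was 0.0264. With the SH2 libraries exchanged, the split that gave the 1102 genes, it was 0.589, so that call would end. The other 6 splits put both libraries of some line together, and over all 10 the highest other values were 63 genes, 1882 genes and 12 lists, while the smallest other adjusted p of the cell cycle list was 1.8e-10. Over all 10, as large a value came from 10 splits for the genes called, 8 for those at an unadjusted p under 0.05, 7 for the lists and 2 for the cell cycle list. The split that called 63 genes put both NC libraries with control SH2, so beside the knockdown term it set the SH2 control library against the other 3 shRNA libraries. A structure of the samples in which that library stood apart would be enough for such a count. The split at 1.8e-10 set the stretched SH3 library against the other 3 in the same way.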

How the results depend on the processing

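The correction for GC content and length and the list tests without single libraries were added after the data were seen. The 0 calls for stretch over the 3 lines and for shRNA against NC at rest held in all alternatives run, and IL11RA kept its direction with median-ratio scaling. The block could not be fitted for shRNA against NC. The block changed the gene counts for stretch in NC (7 genes, 13 with the correction), stretch in the shRNA lines (10, and 25) and the difference (14, and 21), the chemokine list then passed in NC and in the shRNA lines and the TGF-beta list in the shRNA lines, and the block changed no other call. Leaving out a shRNA library from the fit of the 4 groups left 1 residual degree of freedom, from the remaining pair of shRNA libraries. Counts and calls therefore also moved where the library left out had no part in the comparison. For the remaining shifts the cause was not tested. Stretch in the shRNA lines gave 1 gene at an FPKM of at least 5, and the difference 0 with the correction alone. Leaving out 1 library gave 0 to 1 genes for stretch in NC, 0 to 20 in the shRNA lines (20 without the SH3 control, 6 without the SH2 control), 0 to 4 for shRNA against NC under stretch (4 without either shRNA control) and 0 to 4 for the difference (4 without the SH2 control). The rule of 2-fold with stretch in all lines, 3 genes, gave 9 with a pseudocount of 0.1, 1 at an FPKM of at least 5, 15 at 1.5-fold and 16 to 39 with a line left out. The rule for both shRNA lines, 16 genes, gave 45, then 95 at 1.5-fold and 55 to 103 with a line left out. Fewer lines make both rules easier to meet. Of the list calls, 0 were left in each of the 6 comparisons with an estimated correlation, a test that hardly any list could pass with so few libraries. With the correction 3 of 5 lists passed for shRNA against NC at rest. Without single libraries the number of lists was 2 to 7 for stretch over the lines, 3 to 4 in NC, 3 to 8 in the shRNA lines, 4 to 7 and 6 to 9 for shRNA against NC at rest and under stretch and 2 to 7 for the difference. The adjusted p of the SRF and MRTF targets in the shRNA lines ranged from 0.00061 to 0.999, and the direction turned without the SH2 control. Single genes and lists beyond these counts moved in 148 cases, stayed as they were in 2181, passed newly in 99, no longer passed in 69 and turned in 1. Unknown depth limits what can be said of low genes such as IL11RA.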

Other observations

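Further members of the gene lists had the following values. The integrin ITGA8 was at 5.51, 0.84 and 2.00 FPKM at rest in NC, SH2 and SH3 and at 4.005, 1.91 and 1.74 under stretch. The stretch channel gene PIEZO1 was at 6.44, 12.4 and 9.78 FPKM at rest and 7.56, 8.77 and 9.65 under stretch. PSAT1, an enzyme of serine synthesis, was at 21.1, 18.3 and 44.7 FPKM at rest and 21.2, 46.9 and 48.1 under stretch. The metallothionein MT2A was at 124, 485 and 363 FPKM at rest and 193, 230 and 413 under stretch. CTGF, a YAP target, was at 66.9, 309 and 72.2 FPKM at rest and 69.7, 97.2 and 75.3 under stretch, so the SH2 control library stood apart. The same library held the highest MMP3 value, 1004 FPKM, against 228 to 473 in the other 5. The cytokine IL6 was at 6.72, 8.97 and 48.2 FPKM at rest and 12.4, 18.0 and 56.8 under stretch.

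Lists with no call in any of the 6 comparisons had these smallest camera adjusted p-values. They were 0.710 for contractile and myofibroblast genes, 0.155 for collagen processing and crosslinking, 0.102 for protease inhibitors, 0.595 for the IL6 family, 0.192 for STAT3 targets, 0.102 for YAP and TEAD targets, 0.139 for immediate early genes and 0.107 for TGF-beta ligands and targets. They were 0.598 for hypoxia and glycolysis, 0.172 for ER stress and amino acid response, 0.0995 for heat shock genes, 0.440 for oxidative stress and metallothionein genes, 0.235 for integrins, 0.401 for stretch channels and mechanosensors and 0.142 for replication-dependent histones.

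Markers of other cell types were few in the table. Of the fixed markers, 2 of 9 keratinocyte, 0 of 6 melanocyte, 1 of 7 endothelial, 2 of 7 immune, 4 of 6 smooth muscle and pericyte, 1 of 6 adipocyte and 1 of 6 cartilage genes were listed, and 0 passed the limma threshold over all genes in any of the 6 comparisons. Of the smooth muscle and pericyte markers, 1 passed at rest between the shRNA and NC lines when adjusted over the list alone, CSPG4.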
